A study of Homo sapiens with 7 samples.

How the data were processed

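The data are 7 Illumina bead arrays of H1 human embryonic stem cells, 1 for each of 7 media, taken 2 days after the change of medium. Per the labels, cells grew on matrigel and received a ROCK inhibitor at passage. Samples were grouped by the medium named in the labels.

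The deposited table holds, per the file headers, 1 summary intensity and 1 detection p-value per probe and array for 33866 probes. It is described there as not normalized, and the software that made it is not given in the sources used here. The detection p-values came in equal steps of 1 in 770 (tolerance 0.001, 0 values off a step), as from a rank among negative control beads. A deposited second table holds the submitters' processed intensity values. Set against the first, each column had rank correlation 1 with its own array and at most 0.869 with another. Its values were linear, quantile normalized (within 3.76% of the mean quantiles) and without background subtraction, with medians of 112.4 to 112.5. That table served as an alternative.

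Probes were named through the platform annotation supplied with the data: 19221 had 1 gene symbol, 3 had several and 14642 are unnamed here. Symbols were updated through Entrez identifiers for 19194 probes, which changed 0 symbols, and 27 were kept as given. Between 11722 (E8) and 12632 (hCDL) probes per array were above background at a detection p-value under 0.01. At that limit 14796 probes were above background on at least 1 array and 10365 on all 7.

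Intensities were background-corrected by normexp, with negative controls inferred from the detection p-values and an offset of 16, then quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. Probes above background on at least 1 array were kept, and the probe with the highest mean represented each gene, giving 7982 genes, of which 2036 had several probes. Where a gene was not above background on the dimmer side, the fold was computed against the higher of its own signal and the lowest signal among probes above background on that array, and is given as at least N-fold. Where only some arrays of a tested group were above background, their number is given.

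Each medium was set against E8 by the log2 difference, counted at 1.5-fold and 2-fold without a test, since each medium has 1 array. The scatter was gauged by the double difference of E8, Albumin, LPA and LPA + Albumin divided by the square root of 2. Tests used limma with an intensity trend in the empirical Bayes prior and Benjamini-Hochberg adjustment, called at 0.05. An additive model of albumin, LPA and lipid mixture was fitted to 6 arrays (all but AlbuMAX), with each factor present on 2 arrays and 2 residual degrees of freedom. Its error is the interaction of LPA with albumin and the difference of CDL from hCDL, so the arrays are not replicates of a medium, and the p-values measure departures from additivity rather than spread between cultures. AlbuMAX, Albumin and LPA + Albumin were also tested as 3 arrays against the other 4, with 5 residual degrees of freedom. There the error holds what the other supplements do.

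Of 40 gene lists, 35 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01 and with an estimated correlation. Per medium, a list's median was placed among 10000 random lists of the same size matched on mean signal in 20 classes. List medians and their random lists were also taken with genes not above background raised to the array's lowest signal above background, an alternative chosen after seeing the data. The lists, models, thresholds and alternatives were fixed before the data were examined, except the comparisons that the text says were added later, which were set up by the same rules. Genes were named by a rule: per medium the 8 highest and 8 lowest genes above background where they were higher, and up to 4 members per list with the largest differences; per tested contrast up to 10 genes in each direction with the largest changes among those passing, or else those with the smallest p; and POU5F1, NANOG, SOX2, HMGCS1, INSIG1, SCD and the LPA receptors always, with 1 further gene that is not reported here. Further list members are named in the text as examples of those that passed. Some genes that the rule also names are left out for length. Correlations of fold changes were taken between differences that share no array, because differences from E8 share its chance values.

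The steps were tested on simulated data in which 200 of 7982 genes were changed. The simulated errors were normal, independent between genes and of the fit's own variances, and the added effects were additive. The real arrays can hold interactions and differences shared across genes. The rates below therefore check the steps and do not measure the error in these data. For albumin 90% of 2-fold and 100% of 4-fold changes were recovered with 12 false calls; for LPA 93% and 100% with 10; for a lipid mixture 83% and 100% with 8; and for 3 arrays against 4, 86% and 100% with 10.

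Alternatives covered no background correction, centring on the median, cyclic loess, an offset of 50, the submitters' processed values, other filters on dim probes, the mean of a gene's probes, other controls, a prior without trend, other sets of arrays and leaving out each array in turn. Where that leaves a factor with 1 array, the lone array is assumed to vary like the others. In the additive model, without 1 of E8, LPA, Albumin and LPA + Albumin, the error is CDL against hCDL alone. The LPA coefficient is then LPA minus E8 (without Albumin or LPA + Albumin) or LPA + Albumin minus Albumin (without E8 or LPA). The albumin coefficient is Albumin minus E8 (without LPA or LPA + Albumin) or LPA + Albumin minus LPA (without E8 or Albumin). Fits with the same coefficient are not separate checks. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No array was left out, and slides were not known. The number of arrays limits the precision.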

Results

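Gene expression was measured in H1 cells, an established human embryonic stem cell line, grown for 2 days in E8, a defined albumin-free medium for pluripotent cells, or in E8 with one of 6 supplements. The supplements were 1.6% AlbuMAX (a lipid-rich bovine albumin), 1% albumin, 1% CDL (a chemically defined lipid concentrate), hCDL (a homemade lipid mixture at 0.1x), 1 μM LPA (lysophosphatidic acid, a signalling phospholipid with its own cell-surface receptors), and 1 μM LPA with 1% albumin. For hCDL the labels disagree, since the sample title gives 0.01% in place of 0.1x. Each of the 7 media was measured on 1 Illumina bead array, so no medium has replicates, and the number of arrays limits the precision. Between 34.6% of the 33866 probes (E8) and 37.3% (hCDL) were above background, and the raw median intensity ran from 108.5 in E8 to 116.9 in hCDL. The values below are log2 differences of normalized intensity over 7982 named genes. Differences of a single medium from E8 have no test, while the effects of LPA, albumin and lipid mixtures across several media were tested with limma.

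AlbuMAX, LPA and LPA with albumin set the cells apart from E8 by more genes than the other 3 supplements did. LPA with albumin differed from E8 at 1.5-fold in 1320 genes (760 higher, 560 lower), AlbuMAX in 1074 (614 higher, 460 lower) and LPA in 851 (516 higher, 335 lower). CDL differed in 512 genes (261 higher, 251 lower), albumin in 423 (220 higher, 203 lower) and hCDL in 382 (215 higher, 167 lower). As a yardstick for scatter between arrays, the double difference (LPA + Albumin minus LPA) minus (Albumin minus E8), scaled to a single difference, passed the same threshold in 468 genes (269 higher, 199 lower). The counts for albumin and hCDL lay below that yardstick and that for CDL slightly above it. The yardstick contains Albumin minus E8, so it is not independent of the albumin count. It also holds any interaction of LPA with albumin, and 376 of its 468 genes lay in the dimmest of 3 equal classes of signal.

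**Figure D1:**
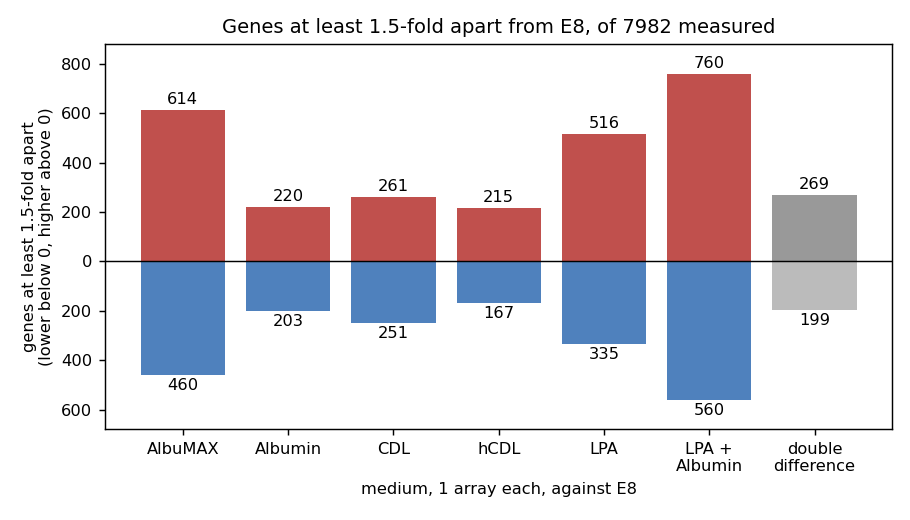
Number of genes (y axis) at least 1.5-fold higher or lower than in E8 in each of the 6 supplemented media, with the double difference used as a yardstick for scatter (x axis). LPA + Albumin (1320 genes), AlbuMAX (1074) and LPA (851) stand above the yardstick of 468 genes, and the other 3 media lie near it, each bar resting on 1 array per medium.

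The balance of higher against lower genes moved with the scaling of the arrays. Without background correction, 222 genes were higher and 73 lower in AlbuMAX, 150 and 22 in LPA, 333 and 94 in LPA with albumin, 30 and 4 in CDL, 5 and 11 in albumin, and 1 and 3 in hCDL. The submitters' processed values gave 221 and 75, 147 and 23, 332 and 95, 30 and 4, 5 and 11, and 1 and 3 for the same media in that order. With the arrays centred on their median in place of quantile normalization, 606 genes were higher and 244 lower in LPA, 1004 and 358 in LPA with albumin, 329 and 143 in albumin, and 320 and 111 in hCDL. A larger background offset of 50 gave 335 and 157 in AlbuMAX, 250 and 84 in LPA, and 22 and 32 in albumin.

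The comparison across media asked which genes differed with LPA once albumin and the lipid mixtures were accounted for. The largest increases with LPA included 3 muscle actin genes. ACTA1, skeletal muscle alpha-actin, rose by 4.26 (SE 0.19, limma adjusted p = 7.1e-07), ACTC1, cardiac alpha-actin, by 4.18 (SE 0.206, limma adjusted p = 1.03e-06) and ACTG2, smooth muscle gamma-actin, by 4.07 (SE 0.222, limma adjusted p = 2.42e-06). ANXA1, a phospholipid-binding annexin, rose by 6.41 (SE 0.314, limma adjusted p = 1.03e-06). It was above background on both LPA arrays and on 2 of the 4 arrays without LPA. These actin genes are close paralogs, and signal shared between their probes was not tested. CAV1, the coat protein of caveolae, rose by 3.41 (limma adjusted p = 5.64e-07).

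Across the 6 arrays other than AlbuMAX, 875 genes passed a limma adjusted p of 0.05 for LPA, of which 530 rose and 345 fell. Of these, 184 rose and 21 fell by at least 2-fold. Cyclic loess normalization gave 597 that rose and 240 that fell, and the balance tilted further up without the Albumin array (138 and 19) and without the LPA + Albumin array (126 and 25). The other strongest increases included genes not above background on any of the 4 arrays without LPA, for which only a bound can be given. TWIST1, a transcription factor of mesenchymal and neural crest cells, rose at least 17.2-fold (limma adjusted p = 1.08e-05), and the long noncoding RNA SFTA1P at least 16.4-fold (limma adjusted p = 9.61e-06). GARIN1B rose at least 13.2-fold, NPPB, the precursor of brain natriuretic peptide, at least 10.7-fold, and MYOF, a membrane repair protein, at least 9.13-fold. IGFBP7, a secreted binding protein for insulin-like growth factors, rose by 3.75 (SE 0.289), with 3 of the 4 arrays without LPA not above background.

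The decreases with LPA were smaller. SCARNA8, a small Cajal body RNA, fell by 1.51 (SE 0.212, limma adjusted p = 0.00127), and EBF2, a transcription factor, fell by 1.46 (SE 0.271, limma adjusted p = 0.00677). ALDH1A1, which makes retinoic acid, fell at least 1.75-fold, the neuronal reticulon RTN1 at least 1.96-fold, MAGEA4 at least 1.53-fold and LINC01844 at least 1.48-fold. The histone gene H2BC9 fell by 1.31 (SE 0.14), the intelectin gene ITLN2 fell by 1.29 (SE 0.144), GSN, an actin-severing protein, fell by 1.24 (SE 0.219), with 1 of the 2 LPA arrays not above background, and SPTSSB, a subunit of the enzyme that starts sphingolipid synthesis, fell by 1.22 (SE 0.224). Among the genes named in advance, INSIG1, a sterol sensor of the endoplasmic reticulum, fell by 0.49 (SE 0.0911, limma adjusted p = 0.00674). With the mean of its probes, the INSIG1 coefficient was -0.31 and did not pass (limma adjusted p = 0.112), nor did it pass without an intensity trend (limma adjusted p = 0.103). Of the decreases named here, EBF2, GSN, LINC01844, MAGEA4, RTN1 and SPTSSB did not pass without the Albumin array (limma adjusted p from 0.163 for GSN to 0.228 for RTN1) or without the LPA + Albumin array (from 0.139 for GSN to 0.202 for RTN1). ALDH1A1 and SCARNA8 did not pass without the Albumin array (limma adjusted p = 0.0617 and 0.0666). Without an intensity trend these genes other than ALDH1A1 did not pass (limma adjusted p from 0.0551 for SCARNA8 to 0.0971 for EBF2), nor did RTN1 with the mean of its probes (limma adjusted p = 0.0679).

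Of 35 gene lists with at least 5 measured genes, 11 passed for LPA in camera, limma's competitive list test, at its preset correlation, 10 of them upward. With an estimated correlation 0 passed (1 list at an unadjusted p under 0.05). The list of SRF (serum response factor) and actin cytoskeleton genes led, with 12 of 15 measured genes rising, 13 when adjusted over the list alone, and none falling (camera adjusted p = 2.32e-15, adjusted p = 0.531 with an estimated correlation). They included ACTA2, smooth muscle alpha-actin, at 3.10 (2 of the 4 arrays without LPA above background), the myosin light chain MYL9 at 2.51, the calponin CNN1 at 2.46 (3 of the 4 above background) and the tropomyosin TPM1 at 1.10. Of 9 measured targets of YAP and TEAD, a transcription complex that responds to cell shape and tension, 5 rose, also 5 adjusted over the list alone, and 4 did not pass (camera adjusted p = 1.81e-06, adjusted p = 0.531 with an estimated correlation). ANKRD1, not above background without LPA, rose at least 3.18-fold, the receptor kinase AXL by 1.75 and tissue factor F3 by 1.29. Of 11 measured immediate early genes, which respond quickly to growth signals, 7 rose, also 7 adjusted over the list alone, among them JUN at 1.98 and FOSL1, not above background without LPA, at least 2.05-fold (camera adjusted p = 7.15e-05, adjusted p = 0.531 with an estimated correlation). ANKRD1, FOSL1 and F3 did not pass without the Albumin array (limma adjusted p = 0.0748, 0.0707 and 0.163) or without the LPA + Albumin array (0.101, 0.0869 and 0.2).

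Targets of Nodal and p53 rose with LPA as well. In the Nodal and TGF-beta list, 5 of 8 measured genes rose, also 5 adjusted over the list alone, and 3 did not pass (camera adjusted p = 2.49e-05, adjusted p = 0.531 with an estimated correlation). These were the Nodal antagonists LEFTY2 at 2.45, LEFTY1 at 1.19 and CER1 at 2.24 (1 of the 4 arrays without LPA above background), with PMEPA1 at 0.65. The stress cytokine GDF15, not above background without LPA, rose at least 6.13-fold. In the p53 list, which shares GDF15, 7 of 11 rose, 9 adjusted over the list alone (camera adjusted p = 1.64e-09, adjusted p = 0.531 with an estimated correlation). The cell cycle inhibitor CDKN1A rose by 2.72, the apoptosis regulator BAX by 1.00 and SESN1 by 0.71. Of 18 measured genes of G2 and mitosis, 3 fell, 4 adjusted over the list alone (camera adjusted p = 0.00965, adjusted p = 0.553 with an estimated correlation): topoisomerase TOP2A fell by 0.50, the mitotic kinesin CENPE fell by 0.48 and cyclin CCNB1 fell by 0.33. PMEPA1, SESN1, TOP2A, CENPE and CCNB1 did not pass without the Albumin array (limma adjusted p from 0.09 for SESN1 to 0.385 for CCNB1) or without the LPA + Albumin array (from 0.101 for SESN1 to 0.379 for CCNB1). CCNB1 also did not pass without CDL (0.0572) or hCDL (0.0571), without background correction (0.0542), with median centring (0.0917) or with cyclic loess (0.0798).

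Camera called 5 other lists for LPA, all upward. In the naive pluripotency list 1 of 5 rose, 2 adjusted over the list alone (camera adjusted p = 0.00965). This gene was NLRP7, an NLR family gene of oocytes and early embryos, at 1.26. In the interferon list 2 of 9 rose, 3 adjusted over the list alone (camera adjusted p = 0.00965), namely ISG15 at 1.29 and HLA-B at 1.03. In the antioxidant list of NRF2 targets 3 of 11 rose, 4 adjusted over the list alone (camera adjusted p = 0.0178), led by NQO1. Among feedback targets of ERK signalling 2 of 5 rose, PHLDA1 at 1.87 and cyclin CCND1 at 0.55, 3 adjusted over the list alone (camera adjusted p = 0.0194). In the fibroblast list 2 of 5 rose, the collagen gene COL6A3 at 1.20 and the collagen crosslinker LOX, not above background without LPA, at least 1.97-fold, 3 adjusted over the list alone (camera adjusted p = 0.0351). NLRP7, HLA-B, CCND1 and LOX did not pass without the Albumin array (limma adjusted p = 0.156, 0.0873, 0.0798 and 0.187) or without the LPA + Albumin array (0.194, 0.108, 0.0789 and 0.213). For each of these 5 lists the adjusted p = 0.531 with an estimated correlation.

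The LPA tests rest on 2 residual degrees of freedom, which hold the interaction of LPA with albumin and the difference between CDL and hCDL, and on the variance prior shared across genes. The count fell to 162 without an intensity trend in the prior, to 512 without a filter on dim probes, to 157 without the Albumin array and to 151 without the LPA + Albumin array, and it was 0 in limma (1010 at an unadjusted p under 0.05, against 2074 in the additive model) when AlbuMAX was added to the fit as a further albumin medium. Of the 79 list members that passed for LPA, 34 kept their call without the Albumin array, 69 without E8, 26 without an intensity trend and 62 without a filter on dim probes. Without Albumin the LPA coefficient is LPA minus E8 alone, as it is without LPA + Albumin. Without E8 it is LPA + Albumin minus Albumin alone, as it is without LPA.

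LPA was also viewed through differences that share no array. The LPA coefficient of the additive model is the mean of LPA minus E8 and LPA + Albumin minus Albumin. The agreement of these differences therefore rests on the same arrays as the limma calls and is not separate support for them. Across genes, which are not independent replicates, LPA minus E8 correlated with LPA + Albumin minus Albumin at Pearson r = 0.653 (Spearman rho = 0.494). At least 2-fold higher in both were 116 genes, against 5.45 for independent lists, and 6 were lower in both, against 0.44. On the single arrays, ANXA1 was 46.5-fold higher in LPA than in E8 and 85.6-fold higher in LPA with albumin. ACTA1 was 13.1-fold and 27.8-fold higher, ACTC1 12.3-fold and 29.8-fold, TWIST1 at least 9.83-fold and at least 26-fold, and SFTA1P at least 8.65-fold and at least 26.9-fold. IGFBP7 was at least 6.36-fold higher in LPA and at least 17.8-fold higher in LPA with albumin.

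**Figure D2:**
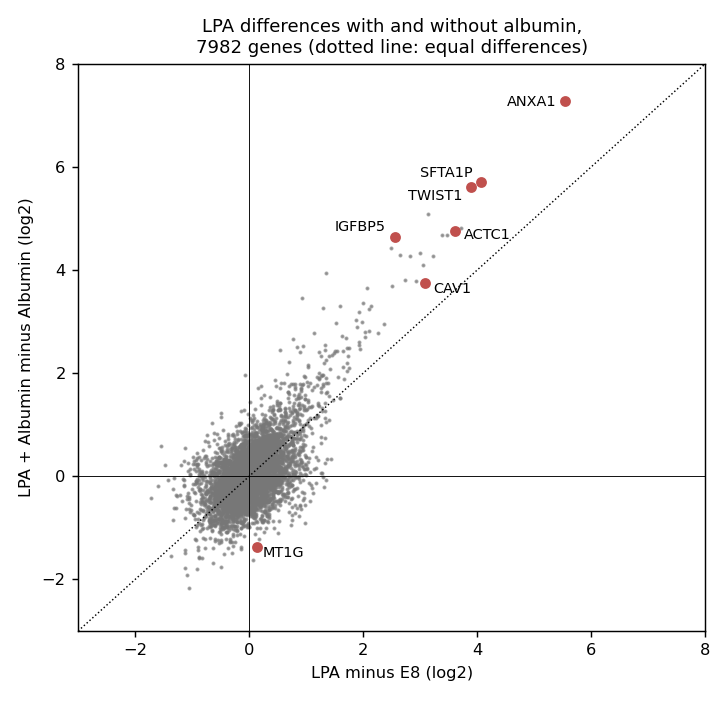
Log2 difference of each of the 7982 genes in LPA minus E8 (x axis) against LPA + Albumin minus Albumin (y axis), pairs that share no array; each point is a gene, red points are genes named in the text, the dotted line marks equal differences, and signals not above background, such as TWIST1 and SFTA1P without LPA, are plotted as measured. The Pearson correlation across genes was 0.653, and 116 genes were at least 2-fold higher in both.

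LPA with albumin was set against LPA alone. The count of genes 1.5-fold apart with LPA as the control was fixed before the data were examined. The fuller description of this pair was added after the data were seen. LPA + Albumin was at least 1.5-fold higher in 349 genes and lower in 244, a total of 593 against the yardstick of 468. The yardstick contains this same difference, so it is not an independent measure of scatter here. IGFBP5, another binding protein for insulin-like growth factors, was 3.81-fold higher, NPPB 3.33-fold and the BMP antagonist GREM1 3.23-fold. The YAP and TEAD list had a median of 0.89 and the SRF and actin list a median of 0.47, both at percentile 100 among 10000 random lists matched on signal. The p53 list (median 0.50) and the Nodal and TGF-beta list (median 0.39) also lay above their random ranges. The core pluripotency list lay at -0.16, at percentile 1.26. On the lower side, the metallothionein gene MT1G was 10.2-fold lower, MT1H 7.4-fold and MT1E 6.2-fold.

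The albumin comparison asked which genes differed with albumin when LPA and the lipid mixtures were accounted for. Metallothioneins, small proteins that bind zinc and copper and are induced by free zinc, fell with albumin. MT1G fell by 2.58 (SE 0.247), MT1H fell by 2.27 (SE 0.222), MT1E fell by 2.05 (SE 0.205) and MT1F fell by 1.55 (SE 0.156), each at a limma adjusted p = 0.00133. MT1X fell by 1.43 (SE 0.117, limma adjusted p = 0.000817) and MT2A fell by 1.20 (SE 0.135, limma adjusted p = 0.0033). Of the 7 measured genes in the list of metallothioneins and zinc, 6 fell, also 6 adjusted over the list alone, and the zinc-sensing factor MTF1 did not pass (camera adjusted p = 1.87e-23, adjusted p = 0.751 with an estimated correlation). Metallothionein genes are near-identical paralogs, and signal shared between their probes was not tested. With LPA 2 of them fell as well: MT1X fell by 0.64 with LPA (SE 0.117, limma adjusted p = 0.00655) and MT1F fell by 0.54 (SE 0.156, limma adjusted p = 0.0499), 3 of 7 fell adjusted over the list alone, and camera did not call the list (adjusted p = 0.151). Without the Albumin array neither MT1X nor MT1F passed for LPA (limma adjusted p = 0.137 and 0.706), nor without LPA + Albumin (0.127 and 0.701), and MT1F did not pass in 4 of the 5 other scalings (0.053 to 0.0712). The list median was -0.86 in LPA + Albumin minus Albumin, at percentile 0 of the random lists, and 0.04 in LPA minus E8.

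In all, 8 genes passed for albumin in limma, against 497 at an unadjusted p under 0.05, where 399 would be reached by chance. Beside the 6 metallothioneins, TXNIP, a glucose-responsive inhibitor of thioredoxin, rose by 1.46 (SE 0.211, limma adjusted p = 0.0257). RNA18SN5, a ribosomal RNA gene, fell by 0.77 (SE 0.109, limma adjusted p = 0.0254). The next genes did not pass, among them PWAR5 at -0.77 (limma adjusted p = 0.0713), the tight junction gene CLDN11 at 0.76 (limma adjusted p = 0.22) and the ribosomal protein gene RPL8 at -0.46 (limma adjusted p = 0.169). Camera also called the SRF and actin list (adjusted p = 8.01e-05), the YAP and TEAD list (adjusted p = 0.00144) and the p53 list (adjusted p = 0.00652) upward, with 0 genes passing in limma in each (3, 3 and 2 at an unadjusted p under 0.05) and, adjusted over the list alone, 1, 0 and 0. All 3 had an adjusted p = 0.751 with an estimated correlation. The count of 8 went to 0 in limma without an intensity trend in the variance prior (524 at an unadjusted p under 0.05). It was 21 without the E8 array, where the albumin coefficient is LPA + Albumin minus LPA alone, as it is without the Albumin array. TXNIP did not pass when any of the 4 arrays E8, LPA, Albumin or LPA + Albumin was left out, with limma adjusted p = 0.137, 0.134, 0.155 and 0.176. RNA18SN5 did not pass without E8 or without Albumin (limma adjusted p = 0.125 and 0.11), nor MT2A without LPA (limma adjusted p = 0.0731). Without a filter on dim probes neither TXNIP nor RNA18SN5 passed (limma adjusted p = 0.182 and 0.0781). PWAR5 passed without CDL (limma adjusted p = 0.0291) or without hCDL (0.0315), as did RPL8 (0.032 and 0.0315), and CLDN11 passed with median centring (0.0412).

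On the single arrays, albumin against E8 showed the same 6 metallothioneins at least 1.5-fold lower, with a list median of -1.24. MT1H was 3.14-fold lower, MT1E 2.77-fold and MT2A 2.37-fold. TXNIP was 3.21-fold higher and the thioredoxin-domain gene TXNDC11 2.20-fold. Most of the other extreme genes were above background in only 1 of the 2 media: NOC2LP2 was at least 2.26-fold higher, SPMIP5 at least 1.76-fold, APRG1 at least 1.42-fold, LTBP2, a matrix protein that binds microfibrils, at least 1.4-fold, PML, the organiser of nuclear bodies, at least 1.38-fold and SMIM22 at least 1.23-fold. The DNA repair gene APLF was at least 2.87-fold lower, the noncoding RNA PART1 at least 1.97-fold and the lysosomal activator GM2A at least 2.15-fold. ICAM4 was at least 2.23-fold lower by its brightest probe and 0.82 higher by another. The SRF and actin list, called upward for albumin across media, had a median of 0.00 in albumin against E8. The YAP and TEAD list, at -0.13, and the p53 list, at -0.021, were also inside their random ranges there, and their medians in LPA + Albumin minus LPA were 0.89 and 0.50. Hypoxia targets had a median of 0.28, at percentile 99.98, led by the histone demethylase KDM3A at 0.51 and the prolyl hydroxylase subunit P4HA2 at 0.41. Albumin minus E8 and LPA + Albumin minus LPA, which share no array, correlated across genes at Pearson r = 0.0683 (Spearman rho = 0.0309). At least 2-fold lower in both were 6 genes, against 0.157 for independent lists, and these were the same 6 metallothioneins.

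**Figure D3:**
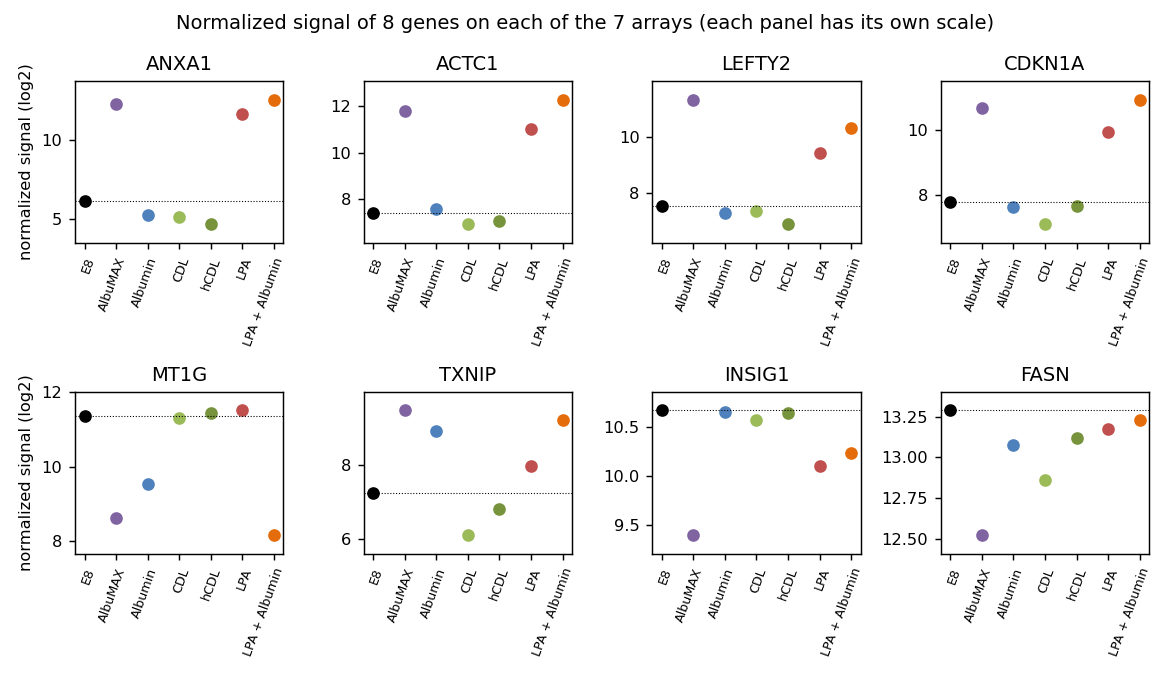
Normalized log2 intensity (y axis, a separate scale in each panel) of ANXA1, ACTC1, LEFTY2, CDKN1A, MT1G, TXNIP, INSIG1 and FASN on each of the 7 arrays (x axis), 1 point per array with no error bars, and a dotted line at the E8 level. MT1G lies between 8.17 and 9.54 on the 3 arrays with albumin or AlbuMAX and between 11.29 and 11.51 on the other 4.

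The question for AlbuMAX was how a lipid-carrying albumin compares with albumin, LPA and lipids given singly. The labels do not give the source of the plain albumin or any lipid bound to it, so it cannot be taken as AlbuMAX without lipid. Among the genes furthest above E8 in AlbuMAX, ANXA1 was 71-fold higher, ACTC1 21.4-fold, ACTA1 19.7-fold and ACTG2 14.5-fold. SFTA1P was at least 18.8-fold higher, GARIN1B at least 16.9-fold, TWIST1 at least 16.1-fold, IGFBP7 at least 14.2-fold, MYOF at least 12.9-fold and NPPB at least 12.6-fold. The metallothioneins were lower, MT1G by 6.73-fold, MT1H 5.91-fold, MT1F 3.59-fold, MT1X 3.04-fold and MT1E 3.01-fold. EBF2 was at least 3.42-fold lower, APLF at least 2.62-fold and ANKRD34A at least 1.98-fold.

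Of the 15 measured SRF and actin genes, 11 were at least 1.5-fold higher in AlbuMAX and none lower, with a list median of 0.87. Of 9 YAP and TEAD targets, 6 were higher, with a median of 1.07, among them AXL at 4.07-fold. Of 8 Nodal and TGF-beta targets, 5 were higher, with a median of 1.19. LEFTY2 was 13.8-fold higher, LEFTY1 3.39-fold, GDF15 at least 5.36-fold and CER1 at least 2.13-fold. Of 11 p53 targets, 6 were higher, with a median of 0.72, led by CDKN1A at 7.39-fold. All 4 medians lay at percentile 100 of the random lists. With genes not above background raised to the array's floor, the medians were 0.87, 1.07, 0.85 and 0.72 in the same order.

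Genes of lipid synthesis were lower in AlbuMAX. Of 11 measured genes of fatty acid synthesis and desaturation, 2 were at least 1.5-fold lower and none higher with dim genes at the floor (3 lower by the measured signals), and the list median of -0.46 lay at percentile 0 of the random lists (-0.39 with dim genes at the floor). ACSS2, which makes acetyl-CoA from acetate, was 2.23-fold lower, fatty acid synthase FASN 1.70-fold, the desaturase FADS1 1.46-fold, SCD, the stearoyl-CoA desaturase, 1.38-fold and the desaturase FADS2 at least 1.21-fold. Cholesterol synthesis genes had a median of -0.31, at percentile 0.04, with 3 of 13 at least 1.5-fold lower. HMGCS1, which makes HMG-CoA, was 1.57-fold lower, ACAT2 1.54-fold and mevalonate kinase MVK at least 1.54-fold. INSIG1 was 2.42-fold lower by its brightest probe. Lipid droplet genes had a median of 0.32, at percentile 98.92 (0.22, at percentile 98.55, with dim genes at the floor in all lists), with the fatty acid binding protein FABP5 1.84-fold and the droplet coat protein PLIN3 1.53-fold higher. The list was also high in LPA against E8, at 0.31 (percentile 99.22, and 0.13 with dim genes at the floor). AlbuMAX minus LPA, added after the data were seen, gave 0.12, inside its random range (percentile 92.68). Across media FABP5 and PLIN3 also passed for LPA, at 0.46 and 0.42 (limma adjusted p = 0.00723 and 0.0181).

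AlbuMAX and LPA with albumin were compared through differences that share no array. The planned pair was AlbuMAX minus E8 with LPA + Albumin minus LPA, at Pearson r = 0.429 across genes (Spearman rho = 0.317). At least 2-fold higher in both were 49 genes, against 1.76 for independent lists. The other comparisons in this paragraph were added after the data were seen. AlbuMAX minus E8 correlated with LPA + Albumin minus Albumin at Pearson r = 0.717 across genes (Spearman rho = 0.54), with 166 genes at least 2-fold higher in both, against 7.52 for independent lists. AlbuMAX minus CDL correlated with LPA minus E8 at Pearson r = 0.563, with 107 genes higher in both, against 4.6. AlbuMAX set directly against LPA + Albumin differed at 1.5-fold in 409 genes (171 higher, 238 lower), under the yardstick of 468. The yardstick contains the LPA + Albumin array and any interaction of LPA with albumin. It can therefore overstate scatter, and a count under it does not show that the 2 media are alike. In AlbuMAX minus LPA + Albumin the fatty acid list had a median of -0.48, the cholesterol list -0.43 and the list of sterol sensing and uptake -0.46, each at percentile 0 of the random lists, and ACSS2 was 2.3-fold lower. The sterol sensing list was less consistent. In the planned comparison with E8 it lay inside its random range, at -0.14 (percentile 13.36), as in AlbuMAX minus Albumin, at -0.21 (percentile 5.06). In AlbuMAX minus LPA it lay below its range, at -0.17 (percentile 1.53). Against LPA + Albumin, lists of the LPA response were lower too, YAP and TEAD targets at -0.48 (percentile 0.01), SRF and actin genes at -0.20 (percentile 0.01) and p53 targets at -0.26 (percentile 0.21), and the metallothionein list was higher, at 0.30 (percentile 99.96). The Nodal and TGF-beta list lay at -0.23, at percentile 1.91, but at percentile 9.51 with dim genes at the floor. The actin-bundling protein LCP1 was 2.73-fold lower, the epithelial 14-3-3 protein SFN 2.45-fold and the cell cycle inhibitor CDKN2B 2.33-fold.

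**Figure D4:**
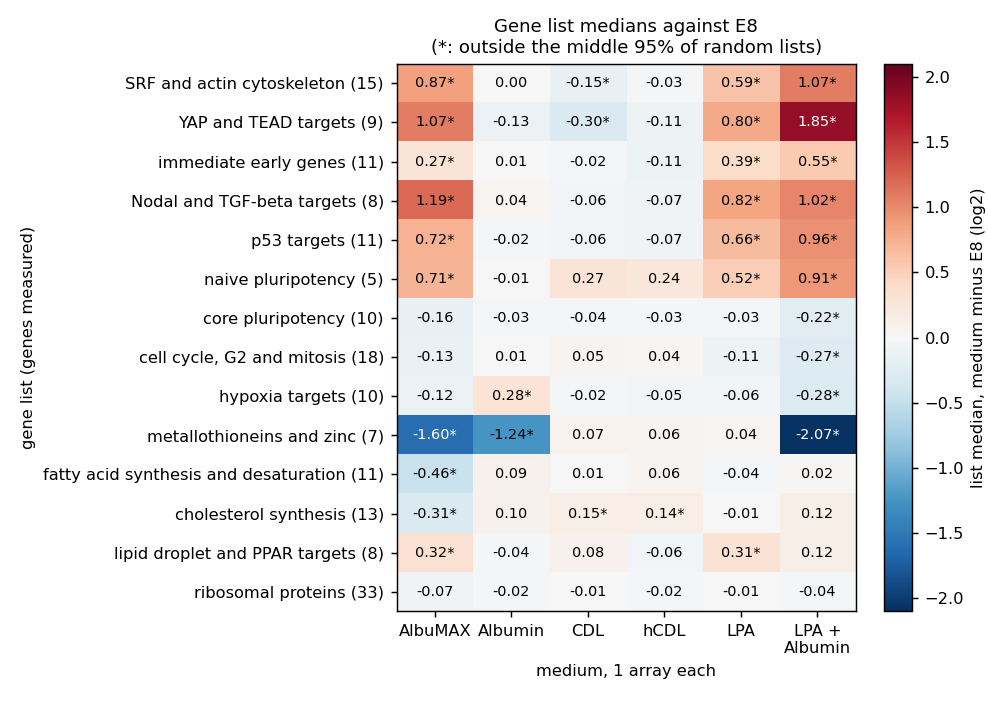
Median log2 difference from E8 of fixed gene lists (y axis) in the 6 supplemented media (x axis), given as colour and as the printed value, with an asterisk where it lies outside the middle 95% of random lists. The metallothionein list is lower in AlbuMAX (-1.60), Albumin (-1.24) and LPA + Albumin (-2.07), and the fatty acid list is lower in AlbuMAX (-0.46) and at 0.024 in LPA + Albumin.

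When the media with albumin or AlbuMAX were pooled, 3 arrays against 4, the 6 metallothioneins fell again. MT1G fell by 2.63 (SE 0.257, limma adjusted p = 0.00501), MT1H fell by 2.34 (SE 0.263, limma adjusted p = 0.0103), MT1E fell by 1.92 (SE 0.178, limma adjusted p = 0.00482), MT1F fell by 1.74 (SE 0.196, limma adjusted p = 0.0103), MT1X fell by 1.49 (SE 0.184, limma adjusted p = 0.0189) and MT2A fell by 1.32 (SE 0.116, limma adjusted p = 0.00482). PWAR5, a noncoding RNA of the Prader-Willi region, fell by 0.79 (SE 0.109, limma adjusted p = 0.0438), a call lost without background correction (limma adjusted p = 0.0516), with median centring (limma adjusted p = 0.0958) and with cyclic loess (limma adjusted p = 0.0581). It was also lost without any 1 of the arrays other than Albumin, with limma adjusted p from 0.0569 without LPA to 0.291 without LPA + Albumin. These were the 7 genes that passed, against 523 at an unadjusted p under 0.05. With the arrays centred on their median 1 gene rose and 6 fell, and with the submitters' processed values 1 rose and 7 fell. TXNIP was at 2.17 and did not pass (SE 0.358, limma adjusted p = 0.134), nor did the flippase gene ATP8B3, not above background on the 4 other arrays and at least 1.37-fold higher (limma adjusted p = 0.134). Both passed without Albumin (limma adjusted p = 0.0428 for each), and TXNIP passed without LPA (0.0127), with median centring (0.0406) and with the submitters' values (0.0477). MT1H, MT1F and MT1X did not pass without E8 (limma adjusted p = 0.101, 0.101 and 0.165), CDL (0.0784, 0.0784 and 0.134), hCDL (0.0853, 0.0853 and 0.141) or a trend in the prior (0.0669, 0.073 and 0.108), and MT1G did not pass without E8 (0.0564). Without AlbuMAX none of the 6 metallothioneins passed, with limma adjusted p from 0.05 for MT2A, above the threshold before rounding, to 0.15 for MT1X.

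Camera called 7 lists in the 3 against 4 comparison. The metallothionein list fell, with 6 of 7 genes passing, also 6 adjusted over the list alone (adjusted p = 2.33e-17, adjusted p = 0.0643 with an estimated correlation). The SRF and actin list (adjusted p = 1.41e-05), the p53 list (adjusted p = 0.000218), the YAP and TEAD list (adjusted p = 0.000328), the Nodal and TGF-beta list (adjusted p = 0.0319) and the list of thyroid hormone and steroid responsive genes (adjusted p = 0.0476) were called upward and the G2 and mitosis list downward (adjusted p = 0.0129). In these 6 lists limma passed 0 genes, also 0 adjusted over the list alone, and at an unadjusted p under 0.05 it gave 1, 1, 2, 0, 1 and 2 in the order named. Each had an adjusted p = 0.622 with an estimated correlation. The Albumin array alone against E8 had the medians of all 6 inside their random ranges, at 0.00 for SRF and actin, -0.021 for p53, -0.13 for YAP and TEAD, 0.04 for Nodal and TGF-beta and 0.011 for G2 and mitosis. The thyroid and steroid list was at 0.24 there, at percentile 97.41, and at 0.0095, at percentile 75.74, with dim genes at the floor. The gene count was 0 in limma without AlbuMAX (244 at an unadjusted p under 0.05), 2 without E8, 3 without CDL, 3 without hCDL and 218 without Albumin, of which 148 rose and 70 fell.

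The lipid mixtures were examined for genes that CDL and hCDL share. In limma 0 genes passed (301 at an unadjusted p under 0.05, where 399 would be reached by chance; smallest adjusted p = 0.99), and camera called 0 of 35 lists (5 at an unadjusted p under 0.05). The smallest p-values belonged to genes with modest values, such as the haem oxygenase gene HMOX2 at 1.00 (SE 0.229), RPL8 at -0.47 (SE 0.0938) and TXNIP at -0.88 (SE 0.235), none of which passed (limma adjusted p = 0.99 for each). With either mixture left out, the other is a lone array assumed to vary like the rest, and the error is the interaction of LPA with albumin alone. Without the hCDL array 20 genes passed, TXNIP among them at -1.23 (limma adjusted p = 0.0115), and 1 passed without E8 and 1 without CDL. CDL minus E8 and hCDL minus LPA, which share no array, correlated across genes at Pearson r = 0.0176 (Spearman rho = 0.0103). At least 2-fold lower in both were 5 genes, against 0.628 for independent lists, and 0 were higher in both, against 0.148. However, hCDL minus LPA also holds the LPA response with its sign reversed, with 179 genes at least 2-fold lower and 31 higher. A pair without LPA, CDL minus E8 with hCDL minus Albumin, was added after the data were seen. It gave Pearson r = 0.0409, with 1 gene lower in both, against 0.0526, and 0 higher, against 0.0905.

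On the CDL array, cholesterol synthesis genes had a median of 0.15, at percentile 99.75, with HSD17B7 at 0.57 and PMVK, phosphomevalonate kinase, at 0.30. The fatty acid list lay at 0.012, with FASN at -0.43. The lipid droplet genes CIDEC, at least 1.25-fold higher, and PLIN5, 1.74-fold higher, led their list. YAP and TEAD targets lay at -0.30, at percentile 0.44, but at -0.052, at percentile 32.48, with dim genes at the floor. Among them AJUBA was at -0.69 and GADD45B at -0.52. SRF and actin genes lay at -0.15, with ACTG2 at -0.84. The highest single genes were the tRNA methyltransferase TRMT2B (at least 2.64-fold), FCF1 (3.12-fold), the leiomodin LMOD3 (2.61-fold), COA8 (2.45-fold), FEM1B (at least 2.38-fold), INSL5 (at least 1.54-fold) and PHACTR1 (at least 1.42-fold). HYKK was 2.74-fold higher by its brightest probe and 0.03 on the log2 scale by another. The lowest were APLF (at least 2.61-fold), ICAM4 (at least 2.03-fold), TM4SF18 (at least 1.85-fold), SNORD69 (at least 1.69-fold), the semaphorin receptor PLXND1 (at least 1.67-fold), TMEM88 (at least 1.5-fold) and AZU1 (at least 1.32-fold). These are values of the brightest probe, and by another probe ICAM4 was at 0.316 and TM4SF18 at -0.265 on the log2 scale. MAP2 was at least 1.68-fold lower by its brightest probe, and its probes differed in direction.

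On the hCDL array, the cholesterol list had a median of 0.14, at percentile 99.61, and HMGCS1 at 0.26 and MSMO1 at 0.24 led it. CDL and hCDL share the E8 array here, and against E8 the list was also at 0.10 in Albumin (percentile 96.99) and 0.12 in LPA + Albumin (percentile 94.48). Against the mean of E8 and LPA, the cholesterol synthesis median was 0.14 in CDL and 0.075 in hCDL. The fatty acid list lay at 0.057, with FADS2 at 0.44. KLF2, a factor of naive pluripotency, was 1.77-fold higher. The highest single genes were HMOX2 (2.20-fold), NOC2LP2 (at least 1.68-fold), LINC01686 (at least 1.51-fold), SERPINA5 (at least 1.44-fold), ANKRD22 (at least 1.27-fold), SMIM22 (at least 1.23-fold) and KRTAP12-3 (at least 1.15-fold). CDH23 was at least 1.3-fold higher, and its difference was -0.31 when dim probes were kept, which changes the probe used. The lowest were APLF (at least 2.88-fold), SLC35D4 (2.78-fold), GM2A (at least 2.16-fold), TMEM201 (at least 2.07-fold), ANXA1 (at least 1.95-fold), SNHG28 (at least 1.84-fold), SMIM45 (at least 1.3-fold) and ATP6V1B1 (at least 1.25-fold). APLF was among the lowest genes in AlbuMAX, Albumin, CDL, hCDL and LPA. Against the mean of CDL and hCDL in place of E8, its difference was 0.057 in AlbuMAX and 0.32 in LPA.

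POU5F1 ranged from 10.29 to 11.02 on the log2 scale and NANOG from 9.98 to 10.34, lowest for both in LPA with albumin. Across media the LPA coefficient was -0.17 for POU5F1 (SE 0.15, limma adjusted p = 0.517) and -0.21 for NANOG (SE 0.0977, limma adjusted p = 0.209). Without the E8 array the POU5F1 coefficient was -0.54 and passed (limma adjusted p = 0.0267). That coefficient is the single difference LPA + Albumin minus Albumin, judged only against the difference of CDL from hCDL. Leaving out the LPA array gives the same coefficient, so it is not a separate check. In the core pluripotency list of 10, the surface protein gene PODXL rose with LPA (0.55) and GDF3, a TGF-beta family ligand, fell by 1.18, and 8 did not pass. PODXL did not pass without the Albumin array (limma adjusted p = 0.172) or without LPA + Albumin (0.165). The list median was -0.22 in LPA with albumin, at percentile 2.18. The receptor genes LPAR1, LPAR2, LPAR3 and LPAR4 were above background on all 7 arrays and LPAR6 on 1. LPAR4 ranged from 7.24 to 8.08 and LPAR2 from 7.28 to 8.11. None of the 5 passed for LPA, with LPAR4 at -0.45 (SE 0.176, limma adjusted p = 0.129) and LPAR3 at -0.41 (SE 0.157, limma adjusted p = 0.127). LPAR4 passed without the E8 array, at -0.84 (limma adjusted p = 0.0175), where the coefficient is again LPA + Albumin minus Albumin alone. SOX2 and LPAR5 were not measured here.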

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

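The test of the metallothioneins against the LPA array, and those of fatty acid synthesis genes in LPA + Albumin, CDL and hCDL, were chosen only after the results were seen, as was the search among unnamed probes. With 1 array per medium, no group was large enough to look for a sample far from the others.

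Probes without a gene name here were used in no comparison of the report. Of 4309 such probes above background on at least 1 array, 13 were at least 2-fold higher with LPA both in LPA minus E8 and in LPA + Albumin minus Albumin, and 1 was at least 2-fold lower in both. The corresponding counts for CDL minus E8 with hCDL minus Albumin were 0 and 0. The probe ILMN_1715748 was higher by 4.22 and 5.48 on the log2 scale, and ILMN_1744381 by 3.26 and 5.03.

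The metallothioneins were lower on the 3 arrays with albumin or AlbuMAX. An unusual E8 array as the cause is argued against by LPA + Albumin minus LPA, which does not use it and gave a median of -2.30 over the 6 genes. Background correction or scaling is argued against by the albumin coefficient, whose median over these genes was -1.80 and at its smallest -1.52 over 6 scalings. In the test of 3 arrays against 4, 2 of the 35 splits of the 7 arrays gave at least as many genes as the real 7, a share too large to exclude chance by that count. The other of the 2, with 1817, sets AlbuMAX, LPA and LPA + Albumin against the rest. This points to a structure of the samples, a profile that AlbuMAX shares with the 2 LPA arrays, rather than to a chance split. The labels give no LPA for AlbuMAX, and its LPA content was not measured here. The remaining 33 splits gave 0 in limma. An effect of albumin and cross-hybridisation among paralogs stay open, and free zinc in the media was not measured here.

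The LPA response was larger beside albumin. Over 245 genes at least 2-fold higher in AlbuMAX than in CDL, a choice that uses none of the 4 arrays compared, the median was 0.89 in LPA minus E8 and 1.48 in LPA + Albumin minus Albumin, and 90.2% of the genes had a larger difference in the second. AlbuMAX is itself an albumin medium, so this choice can favour genes that respond more beside albumin, and part of the gap may come from it. A higher baseline in E8 would need Albumin minus E8 to lie near the negative of the median gap of 0.63, and its median was -0.011. The lowest median gap over 6 scalings was 0.61, which argues against normalization. An effect of albumin on the LPA response was not tested by itself, and a difference between single cultures remains open because each medium has 1 array.

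Fatty acid synthesis genes were lower in AlbuMAX. The shared E8 array is argued against by the other 5 arrays, against which the list median of AlbuMAX was at most -0.39. An LPA-like response as the whole cause is argued against by LPA + Albumin, at 0.024. An effect that every supplied lipid shares is argued against by CDL, at 0.012, and hCDL, at 0.057, at the doses used. The lipids that AlbuMAX itself brings were not tested apart from its albumin and stay open, and a peculiarity of the single AlbuMAX culture or array stays open.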

How the results depend on the processing

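The mean of CDL and hCDL as a control, and list medians with dim genes at the floor, were added after the data were seen; the other alternatives were planned. No paired analysis was possible because each medium has 1 array. A fit with the slide as a block was not run, since the column names give no slide. Signal over background limits dim genes most: 376 of the 468 yardstick genes lay in the dimmest class, and the log2 differences of dim genes shrink without background correction. Centring on the median shifted the median of all genes by 0.134 in Albumin and 0.131 in hCDL. Of the comparisons of list medians with their alternatives, 2531 kept their value, 155 moved and 5 reversed; of those of named genes in single media 1184, 379 and 4; of those of tested genes, list members past the threshold included, 3082 kept their call, 386 lost it, 25 gained it and 0 reversed. The 8 genes called for albumin were the same 8 under each of the 5 other scalings, where for albumin centring on the median added 1 (9 in all).

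Counts of genes 1.5-fold from E8, for AlbuMAX, Albumin, CDL, hCDL, LPA and LPA + Albumin in that order, were 295, 16, 34, 4, 172 and 427 without background correction, 296, 16, 34, 4, 170 and 427 with the submitters' values, 492, 54, 99, 36, 334 and 683 with an offset of 50, and 570, 109, 166, 77, 418 and 789 over genes detected on all arrays. AlbuMAX gave 590 against the mean of E8 and LPA, and LPA + Albumin 593 against LPA. The filter for genes detected on all arrays tests fewer genes, and a control that includes LPA makes another comparison. Otherwise the cause was not tested.

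Of the genes called, albumin had 0 without an intensity trend and 6 to 21 when an array was left out. LPA had 512 without a filter on dim probes, 162 without a trend, 0 with AlbuMAX counted as albumin, and 151 to 919 when an array was left out. A lipid mixture had 0 to 20 when an array was left out. In the test of 3 arrays against 4, 4 passed without a trend, 0 with AlbuMAX left out, and 0 to 218 over all arrays left out in turn. With an estimated correlation camera passed 0 lists for albumin, LPA and 3 against 4 (1, 1 and 2 at an unadjusted p under 0.05). Leaving out arrays gave 1 to 9 lists for albumin, 7 to 12 for LPA, 0 to 5 for a lipid mixture and 4 to 12 for 3 against 4. For a lipid mixture 1 list passed with centring on the median and 2 over genes detected on all arrays. Fewer arrays leave fewer degrees of freedom. That alone does not account for the range in LPA, with 847 genes without E8 and 157 without Albumin, each with 1 array left out. Without Albumin the LPA coefficient is LPA minus E8 alone, a difference of at least 1.5-fold in 851 genes. Without E8 it is LPA + Albumin minus Albumin alone, with 1320 such genes. The fit with AlbuMAX counted as albumin had more arrays, not fewer, and gave AlbuMAX no LPA term. AlbuMAX minus E8 correlated with LPA + Albumin minus Albumin at Pearson r = 0.717, and that fit leaves this shared profile to the error. Without Albumin, the test of 3 against 4 sets only AlbuMAX and LPA + Albumin against the rest. The cause was not tested otherwise.

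Reversed were the BMP list in AlbuMAX (-0.031) and the WNT list in LPA (0.069) without a filter on dim probes, the WNT list in LPA + Albumin against LPA (0.12), the ATF4 list in Albumin centred on the median (0.0103) and against CDL and hCDL (0.000627), APLF against CDL and hCDL in AlbuMAX (0.057) and LPA (0.32), and CDH23 in hCDL (-0.31) at a detection p under 0.05 and without a filter. For CDH23 another probe is used. APLF stood at 6.69 in E8 and between 4.76 and 5.37 on the other arrays, so its reversal comes with leaving E8 out of the control. The WNT list against LPA is another comparison, whose control was itself below E8 in this list. The cause of the other reversals was not tested.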

Other observations

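The comparisons between supplemented media described here, and the count of genes that set 1 array apart, were chosen only after the results were seen.

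Several gene groups not described above differed between media. WNT targets had a median of -0.50 in LPA and -0.46 in LPA + Albumin, below their random ranges, but at -0.25 and -0.29, at percentiles 5.165 and 6.445, with dim genes at the floor in all lists, with the WNT inhibitor NKD1 at least 1.19-fold lower in LPA and at least 1.22-fold lower in LPA + Albumin. APCDD1 was lower in AlbuMAX (-1.32), Albumin (-0.82), LPA (-0.74) and LPA + Albumin (-0.63). Among 5 measured WNT targets, AXIN2 passed for LPA, at -0.44, and did not pass without E8, LPA, Albumin or LPA + Albumin (limma adjusted p = 0.0805, 0.076, 0.0836 and 0.0828). BMP targets had a median of 0.32 in AlbuMAX, at percentile 98.03, which turned to -0.031 without a filter on dim probes, and across media ID1 (0.41) and BAMBI (0.87) rose with LPA while ID2 fell by 0.55. ID1 and ID2 did not pass without Albumin (limma adjusted p = 0.361 and 0.341) or LPA + Albumin (0.364 and 0.329). In the neuroectoderm list, of which 4 genes were measured, NES rose by 1.60 with LPA and FABP7 fell by 1.08, a call lost without Albumin (limma adjusted p = 0.241) or LPA + Albumin (0.219). In the mesendoderm list, of which 3 were measured, none passed for LPA, but 2 fell adjusted over the list alone, and the median LPA coefficient was -0.775.

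Hypoxia targets lay at 0.28 in Albumin and at -0.28 in LPA + Albumin, and LPA + Albumin minus Albumin gave -0.41, at percentile 0.14, with 5 of 10 genes at least 1.5-fold lower and 2 higher. For LPA across media NDRG1 and ADM rose while ANKRD37 and P4HA1 fell. NDRG1, ANKRD37 and P4HA1 did not pass without Albumin (limma adjusted p = 0.0868, 0.306 and 0.414) or LPA + Albumin (0.0982, 0.287 and 0.406), nor NDRG1 and ANKRD37 without E8 (0.0813 and 0.0602) or LPA (0.0924 and 0.0547). TXNIP was higher than in E8 in AlbuMAX (2.24), LPA + Albumin (1.97), Albumin (1.68) and LPA (0.74) and lower in CDL (-1.12) and hCDL (-0.43).

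Genes that were at least 1.5-fold apart from all 6 other arrays numbered 76 for LPA + Albumin, 31 for E8, 31 for AlbuMAX, 28 for Albumin, 26 for CDL, 21 for LPA and 13 for hCDL. APLF, measured by 1 probe, was at 6.69 in E8 and between 4.76 and 5.37 in the other media, 2.5-fold over the next highest array.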
